A study of Drosophila melanogaster with 39 samples.

How the data were processed

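Polyadenylated RNA was sequenced from single heads of adult male *Drosophila melanogaster* of the genotype Cantonized w1118, per the labels, and each library came from one fly. Titles place each sample in 1 of 5 groups: naive Mid, naive High, shocked High, shocked Mid and shocked Low, where High, Mid and Low are classes of place preference. How the classes were bounded is not given in the sources used here. The protocol text (shocks of 60 V for 5 min, an assay at 1.5 h and freezing at 2.5 h) is identical for naive and shocked samples, so naive or shocked was taken from the titles. All labels give one batch date, so batches could not be separated. The extraction protocol of the samples also calls the assay nuclear RNA-seq, and this was left unresolved.

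Per the series design text, the authors extracted total RNA from individual heads, selected mRNA with oligo dT beads, trimmed adaptors with Trimmomatic and aligned reads to dm6 with STAR. They kept primary alignments with a mapping quality of at least 8, counted reads on exons with HTSeq-count and tested differences with DESeq2. The versions of these tools and the strand setting are not given in the sources used here. The deposited count table holds raw counts of reads per gene, and the deposited comparison table holds the authors' log2 fold changes and adjusted p-values (q-values), per the file headers. The count table held 17559 genes. Of 39 labelled samples, 37 had a column of counts; 2 shocked High samples had none and were not analysed here, and 2 columns that matched no sample, B3 and B4, were not used (the labels give the letter B to naive High libraries). The design was written for 39 samples.

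Total counts, in megacounts (M), ranged from 5.01 to 11.32 M per library, with a median of 7.65 M. Group medians were 7.65 M for naive Mid, 7.99 M for naive High, 7.54 M for shocked High, 8.5 M for shocked Mid and 7.21 M for shocked Low. Between 11399 and 12344 genes were detected per library. Between pairs of libraries of the same group the chi-square per gene was 7.79 to 94.2, so no library was a copy of another of its group; pairs across groups were not compared. The median standard error of a log2 fold change was 0.094 for the pooled shock contrast, 0.187 for the interaction and 0.12 to 0.137 for the others.

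Comparisons, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where stated. Genes were filtered with edgeR's filterByExpr by group, which left 10272, and scaled by TMM. One quasi-likelihood model of the 5 groups was fitted to all 37 libraries, and 8 contrasts were tested with Benjamini-Hochberg adjustment at 0.05: shock with High and Mid weighted equally, shock within High, shock within Mid, their interaction, naive High against Mid, and shocked Low against High, Low against Mid and High against Mid. Levels are counts per M (CPM); log2 CPM values used a prior count of 2. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Positions are from Ensembl release 115 in dm6 coordinates. A library was counted on the side of a difference when it lay on that side of the other group's mean. Groups can still overlap where all libraries lie on the side of the difference. Genes were named by their p in the same libraries, so these counts are high by selection and are not separate support.

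Lists were tested with camera at its preset correlation of 0.01, with the correlation estimated from the data and with fry, adjusted over 168 tests (21 lists in 8 comparisons). Member genes were also adjusted over the list alone. The 22 lists were antennal and olfactory markers, antimicrobial peptides and Bomanins, circadian clock, cytosolic ribosomal proteins, detoxification and oxidative defence, fat body and lipid storage, glial, haemocyte, heat shock, immune recognition and signalling, injury with JNK and apoptosis, male dosage compensation RNAs, monoamine, muscle, neuronal activity-regulated genes, neuropeptides, oxidative phosphorylation, pan-neuronal, photoreceptor, sex-biased, starvation with FOXO and sugar metabolism, and Turandot with JAK-STAT targets. The dosage compensation list has 2 members and was too small for a list test. A list score is the mean log2 CPM of its tested members. Scores were compared by permutation, with 100000 resamples where not exact. Pairwise score tests covered only the fat body and antimicrobial lists in chosen pairs of groups. They were not among the tests fixed in advance, and their adjustment over 8 tests does not cover that choice.

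The named-gene rule took, for the pooled shock contrast and shocked Low against High, the 10 higher and 10 lower genes with the smallest p among those passing, and 5 and 5 for every other comparison. Where none passed, the 3 genes with the smallest p were named as not passing. From each list up to 4 members with the smallest p were named among those passing over all genes or over the list alone. The genes roX1, roX2, Yp1, Yp2, Yp3 and w were named as checks of the labels.

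The 7 alternatives fixed in advance were DESeq2's size factors, no low-count filter, a strict filter (at least 50 counts in at least 7 libraries), DESeq2, limma voom with quality weights, only the groups compared, and a block for replicate number. Added after seeing the data were an adjusted p under 0.1, leaving out each library, the fat body score as a covariate, the log2 total count as a covariate, and DESeq2 with its default filtering target of 0.1. DESeq2's independent filtering was aimed at 0.05 in the alternative fixed in advance, and this setting was settled after both results existed. The pipeline was tested on simulated data with known changes: of genes changed 2-fold it called 75.4% within Mid, 57.9% for the interaction and 73.7% for shocked High against Mid, with 8 of 148, 4 of 110 and 7 of 154 calls false. Of genes changed 4-fold it called 95.2%, 90.5% and 96.8%. The simulated genes were independent, while real genes are correlated. These simulated fits gave 148, 110 and 154 calls against 2, 0 and 7 in the real data, which eases the adjusted threshold. Recovery in the real data may therefore be lower.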

Results

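Single heads of adult male *Drosophila melanogaster* were compared between naive and shocked flies and between classes of place preference. The groups held 7 naive Mid, 7 naive High, 6 shocked High, 8 shocked Mid and 9 shocked Low heads, and each library was one head from one fly. The male-specific RNAs roX1 and roX2, which take part in dosage compensation, averaged 1690 CPM (range 988 to 2240) and 93.6 CPM (range 62.0 to 129) over the 37 libraries. The yolk protein genes Yp1, Yp2 and Yp3 averaged 52.9, 34.8 and 127 CPM. The gene w, which encodes an eye pigment transporter and is mutated in the stated genotype, averaged 1.19 CPM (range 0 to 4.95).

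Shock was first compared between shocked and naive heads with the High and Mid classes weighted equally. If the classes come from the assay at 1.5 h, they were set after the shock. Shocked and naive heads of 1 class may then be differently selected flies, which these contrasts cannot separate from an effect of shock. There was no naive Low group, so shocked Low heads entered no shock contrast. Sulf1 (FBgn0040271, dm6 chromosome 3R, 16310542 to 16339575), an extracellular enzyme that removes sulfate groups from heparan sulfate, was 1.22-fold higher in shocked heads. It averaged 103 ± 10.5 CPM in shocked High heads (SD, n = 6) and 102 ± 10.1 CPM in shocked Mid heads (n = 8). In naive High and naive Mid heads it averaged 85.2 ± 5.63 CPM (n = 7) and 83 ± 5.36 CPM (n = 7), and all 14 shocked and all 14 naive libraries lay on the side of the difference. The log2 fold change was 0.29 (SE 0.05) within the pooled contrast, 0.28 at High and 0.30 at Mid, with an interaction of -0.02 (SE 0.10, adjusted p = 0.961). The adjusted p was 0.00846 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and ranged from 0.000979 to 0.0278 over the 7 alternatives.

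Sulf1 was the only one of 10272 tested genes to pass (1 higher, 0 lower), while 647 genes had an unadjusted p under 0.05 against 514 expected by chance. DESeq2 called 8 genes and limma called 3. With 1 library left out, the count was 5 without Naive_Mid 4 or without Shocked_High 2. It was 3 without Naive_Mid 3, Naive_Mid 7, Naive_High 1, Naive_High 5, Shocked_High 3 or Shocked_Mid 2, and 2 without Naive_High 2, Naive_High 3 or Shocked_High 1.

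Among the gene groups fixed in advance, the 11 neuronal activity-regulated genes had 0 members passing over all genes and 3 lower when adjusted over the list alone. These were CG14186 (log2 fold change -0.21, SE 0.05), the transcription factor gene sr (-0.28, SE 0.10) and the nuclear receptor gene Hr38 (-0.34, SE 0.13). Over the 11 genes the median was -0.10, with a camera adjusted p = 0.00342 at the preset correlation and an adjusted p = 0.578 with an estimated correlation. Of 24 monoamine genes, 0 passed over all genes and 2 were lower adjusted over the list alone: Vmat, the vesicular monoamine transporter (-0.21, SE 0.05), and the octopamine receptor gene Octbeta2R (-0.27, SE 0.08). That list's median was -0.10 (adjusted p = 0.000705 at the preset correlation, adjusted p = 0.578 with an estimated correlation). All 17 pan-neuronal genes (median -0.07) and 23 of 25 neuropeptide genes (median -0.13) had negative values, with 0 members passing over all genes or adjusted over the list alone. Their camera adjusted p values were 0.00132 and 5.23e-05 at the preset correlation, and adjusted p = 0.637 and adjusted p = 0.578 with an estimated correlation. Library Shocked_High 3, which had a limma quality weight of 0.39, was the lowest of all 37 for 10 of 17 pan-neuronal, 6 of 25 neuropeptide, 5 of 24 monoamine and 3 of 11 activity-regulated genes. Without it, a fit chosen after seeing the data, the pan-neuronal median was -0.04 (15 of 17 negative; adjusted p = 0.0984 at the preset correlation). The neuropeptide median was then -0.11, the monoamine median -0.08 and the activity-regulated median -0.09, with 1 of the activity-regulated genes lower adjusted over the list alone. Values were positive for 10 of 12 glial genes (median 0.08) and 13 of 15 muscle genes (0.07), with 0 passing over all genes or adjusted over the list alone. Their adjusted p values of 0.0165 and 0.0338 at the preset correlation became adjusted p = 0.578 and adjusted p = 0.701 with an estimated correlation. Haemocyte genes (10 of 13 negative, median -0.07; adjusted p = 0.698) and fat body genes (7 of 11 negative, median -0.02; adjusted p = 0.977) were not called at the preset correlation.

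In the photoreceptor list of 21 genes, 0 passed over all genes and the rhodopsin genes Rh5 (0.41, SE 0.11) and Rh6 (0.34, SE 0.11) were higher adjusted over the list alone. The list's median was -0.01, its mean 0.02 and its camera direction downward (adjusted p = 0.877). Of 26 antimicrobial peptide and Bomanin genes, 0 passed over all genes and CG43202, a Bomanin gene, was higher adjusted over the list alone (1.04, SE 0.28). Over the 26 genes the median was 0.38 (adjusted p = 2.24e-05 at the preset correlation, adjusted p = 0.578 with an estimated correlation). The heat shock list had 0 of 11 members passing over all genes and Hsp70Bc lower adjusted over the list alone (-0.81, SE 0.23); counts for this gene are uncertain because near-identical copies exist. In the injury list 0 of 12 passed over all genes and skl, an apoptosis activator, was lower adjusted over the list alone (-0.60, SE 0.18). In the antennal list 0 of 11 passed over all genes and Ir76b, an ionotropic receptor co-receptor, was higher adjusted over the list alone (0.67, SE 0.18). The antennal median was -0.03 and its mean 0.03.

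Within the Mid class, 2 genes of amino acid and one-carbon metabolism were higher in shocked than in naive heads. Nmdmc (FBgn0010222; dm6 chromosome 3R, 9042508 to 9050555), a mitochondrial folate enzyme, was 3.52-fold higher in shocked Mid heads (95.9 ± 65.2 CPM, SD, n = 8) than in naive Mid heads (27.2 ± 12.7 CPM, n = 7). Asparagine-synthetase (FBgn0041607; dm6 chromosome 3L, 21173118 to 21174973), which makes asparagine, was 1.67-fold higher (117 ± 11.2 against 70.0 ± 9.38 CPM). For both genes all 8 shocked and all 7 naive libraries lay on the side of the difference. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Nmdmc had a log2 fold change of 1.81 (SE 0.32, adjusted p = 0.0216; 0.00017 to 0.061 over the alternatives). Asparagine-synthetase had 0.74 (SE 0.14, adjusted p = 0.0222; 0.00017 to 0.0187 over the alternatives). The Nmdmc call was lost when only the groups compared were fitted (adjusted p = 0.061).

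**Figure D1:**
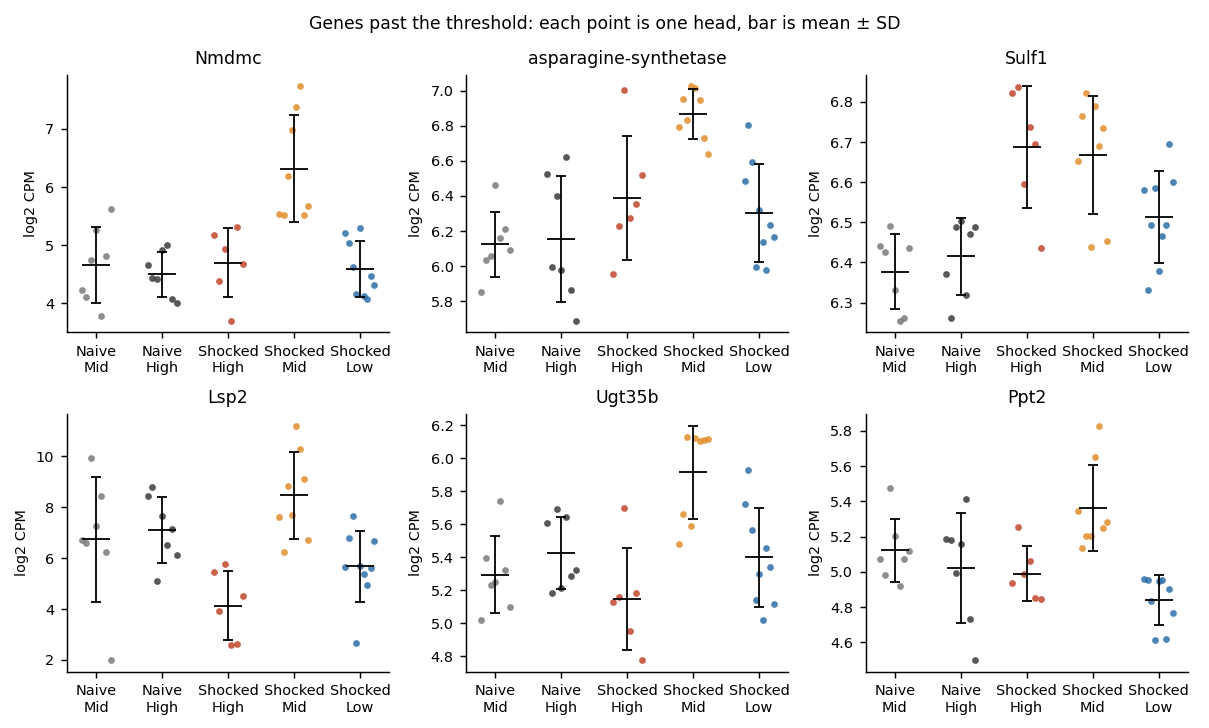
Expression of Nmdmc, asparagine-synthetase, Sulf1, Lsp2, Ugt35b and Ppt2 in each head as log2 CPM, with the mean and SD of the 5 groups. Each point is one library, with n = 7, 7, 6, 8 and 9 for naive Mid, naive High, shocked High, shocked Mid and shocked Low.

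Within Mid edgeR called 2 genes (2 higher, 0 lower), and 1342 genes had an unadjusted p under 0.05 against 514 by chance. DESeq2 called 21 genes (19 higher, 2 lower) and limma 8 (6 higher, 2 lower). A fit of only the groups compared called 14 genes (6 higher, 8 lower), of which 1 was among the 2. With 1 library left out, both genes missed the threshold without Naive_Mid 1 (adjusted p = 0.099), Naive_Mid 2 (0.0732), Naive_Mid 3 (0.0659), Shocked_Mid 4 (0.0592), Shocked_Mid 5 (0.0686) or Shocked_Mid 6 (0.055), which left a count of 0. The count was 4 without Naive_Mid 4 or Shocked_Mid 2 and 6 without Shocked_Mid 8. With the fat body score as a covariate, chosen after seeing the data, neither gene passed: Nmdmc went from 1.81 (SE 0.32) to 1.56 (SE 0.34, adjusted p = 0.133) and asparagine-synthetase from 0.74 (SE 0.14) to 0.60 (SE 0.12, adjusted p = 0.0869). With total count as a covariate asparagine-synthetase did not pass (0.70, SE 0.14, adjusted p = 0.0965).

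Of 11 activity-regulated genes, 6 were lower within Mid adjusted over the list alone, with 0 over all genes. They included CG14186 (-0.25, SE 0.06), sr (-0.46, SE 0.14), Hr38 (-0.50, SE 0.18) and CG11221 (-0.32, SE 0.12). Over the 11 genes the median was -0.18 (adjusted p = 0.00405 at the preset correlation, adjusted p = 0.578 with an estimated correlation). Vmat was 1 of 24 monoamine genes lower adjusted over the list alone, with 0 over all genes. It averaged 297 ± 33.3 CPM in shocked Mid and 377 ± 33.5 CPM in naive Mid heads (log2 fold change -0.34, SE 0.07), and all 8 and all 7 libraries lay on that side. All 17 pan-neuronal genes had negative values (median -0.15; adjusted p = 0.000164 at the preset correlation, adjusted p = 0.591 with an estimated correlation).

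Immune genes gave mixed values within Mid. Of 26 antimicrobial peptide and Bomanin genes, 0 passed over all genes, while 5 were higher and 1 lower adjusted over the list alone. CG43202 (1.56, SE 0.39), CG5778 (0.63, SE 0.18) and CG5791 (0.83, SE 0.30), all Bomanin genes, were among the higher members, and Defensin (Def) was lower (-4.35, SE 1.49). For Def all 8 shocked but only 4 of 7 naive libraries lay on the side of the difference. Bomanins and peptides together had a median of 0.63 and its mean -0.05, and camera pointed upward (adjusted p = 0.000232 at the preset correlation, adjusted p = 0.591 with an estimated correlation). Of 20 immune recognition and signalling genes, 0 passed over all genes and 3 were higher adjusted over the list alone. These were SPE, which processes the Toll ligand (0.69, SE 0.18), the serpin gene nec (0.61, SE 0.20) and the peptidoglycan receptor gene PGRP-LC (0.35, SE 0.12). Each of the 9 Turandot and JAK-STAT target genes tested had a positive value (median 0.90), with 0 passing over all genes or adjusted over the list alone. Their adjusted p = 0.0266 at the preset correlation became adjusted p = 0.637 with an estimated correlation.

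In the detoxification list, 0 of 18 genes passed within Mid over all genes, and 3 were higher and 1 lower adjusted over the list alone. Ugt35b, a UDP-glycosyltransferase (0.63, SE 0.14), the superoxide dismutase gene Sod (0.28, SE 0.09) and the cytochrome P450 gene Cyp6w1 (0.69, SE 0.23) were higher. Gclc, a subunit of the enzyme that starts glutathione synthesis, was lower (-0.17, SE 0.06). CG10924, a phosphoenolpyruvate carboxykinase gene, was 1 of 19 starvation and sugar genes higher adjusted over the list alone (1.27, SE 0.35), with 0 over all genes. Rh5 in the photoreceptor list was higher (0.54, SE 0.16), while Hsp70Bc in the heat shock list (-1.31, SE 0.31) and Yp1 in the sex-biased list (-0.40, SE 0.13) were lower adjusted over the list alone, with 0 over all genes in each list. All 83 ribosomal protein genes had positive values (median 0.21), with 0 passing over all genes or adjusted over the list alone; adjusted p = 9.51e-18 at the preset correlation became adjusted p = 0.578 with an estimated correlation of 0.766. Antennal genes were positive for 10 of 11 members (median 0.59), with 0 passing over all genes or adjusted over the list alone; adjusted p = 0.0186 at the preset correlation became adjusted p = 0.637 with an estimated correlation. Over the same libraries the fat body score, the mean log2 CPM of the fat body list, was 8.60 ± 0.47 in shocked Mid and 8.12 ± 0.65 in naive Mid heads. This difference of 0.47 did not pass (exact permutation p = 0.129, adjusted p = 0.206 over 8 tests).

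Within the High class no gene passed (0 higher, 0 lower) in edgeR, DESeq2 or limma, with 581 genes at an unadjusted p under 0.05 against 514 by chance. The 3 genes with the smallest p did not pass: Ir8a, an ionotropic receptor co-receptor (log2 fold change -3.40, SE 0.81), CG32506 (0.36, SE 0.09) and Sulf1 (0.28, SE 0.07), each with an adjusted p of 0.694 and all 6 shocked and all 7 naive libraries on the side of the difference. Ir8a was near the limit of detection, with 0.109 ± 0.213 CPM in shocked High and 1.26 ± 0.909 CPM in naive High heads. Adjusted over the list alone, Ir8a was lower and Ir76b higher (0.75, SE 0.26) among 11 antennal genes, and the storage protein gene Lsp2 was lower (-2.96, SE 0.88) among 11 fat body genes, with 0 over all genes in both lists. The antennal median was -0.55; without Shocked_High 3 it was -1.03, with 4 antennal genes lower and 1 higher adjusted over the list alone. Leaving out Shocked_High 2 instead, the lowest of all 37 libraries for 7 of these 11 genes, shrank the negative values of odorant-binding protein genes. Values went from -0.66 to -0.41 for lush, -0.77 to -0.51 for Obp83a and -0.55 to -0.28 for Obp19a. Ir8a and Ir76b still passed adjusted over the list alone. All 15 muscle genes had positive values (median 0.19), with 0 passing over all genes or adjusted over the list alone; adjusted p = 0.000179 at the preset correlation became adjusted p = 0.578 with an estimated correlation. Values were negative for 82 of 83 ribosomal protein genes (median -0.14), 16 of 18 detoxification genes (-0.25) and 25 of 30 oxidative phosphorylation genes (-0.06), with 0 passing over all genes or adjusted over the list alone. Their adjusted p values of 1.15e-09, 0.000255 and 0.00319 at the preset correlation became adjusted p = 0.637, adjusted p = 0.578 and adjusted p = 0.667 with an estimated correlation. Without Shocked_High 3 these medians were -0.23, -0.32 and -0.09. Among shocked High heads, Shocked_High 3 had the highest score for these lists and for the antennal list. Leaving it out therefore lowers the shocked High mean of these lists by construction.

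The interaction asked whether the response to shock differed between High and Mid, as the High difference minus the Mid difference. No gene passed in edgeR (0 higher, 0 lower; smallest adjusted p 0.236), with 1265 genes at an unadjusted p under 0.05 against 514 by chance, and 4 genes passed without Shocked_High 3. DESeq2 called 3 genes, or 0 with its default filtering target, and limma 2. The smallest p belonged to Ir8a (-4.58, SE 1.01), CG15739 (-0.86, SE 0.19) and Ugt35b (-0.89, SE 0.20), none passing. For Nmdmc the interaction was -1.56 (SE 0.47, adjusted p = 0.284), with a difference of 0.25 (SE 0.34) within High. For asparagine-synthetase it was -0.50 (SE 0.20, adjusted p = 0.319), with 0.23 within High. A difference between the classes in the response of these 2 genes therefore did not pass the test.

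Of 18 detoxification genes, 9 had a negative interaction value that passed adjusted over the list alone, with 0 over all genes. Ugt35b, Sod (-0.44, SE 0.14), Cyp6w1 (-1.06, SE 0.34) and Cyp6g1, a cytochrome P450 (-0.84, SE 0.27), were among them, and the list's median was -0.52 (adjusted p = 6.08e-06 at the preset correlation, adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, SPE among immune genes (-0.91, SE 0.27), Lsp2 among fat body genes (-4.34, SE 1.14) and Ir8a among antennal genes were lower. So were the sugar genes CG10924 (-1.67, SE 0.52) and Amy-p, an amylase with a near-identical copy (-3.02, SE 0.93). With all 37 libraries none of these lists had a member passing over all genes. In the fat body list 10 of 11 genes were negative, with only Lsp2 passing adjusted over the list alone. The fat body median was -0.66 (camera adjusted p = 0.00564 at the preset correlation, adjusted p = 0.591 with an estimated correlation). Antennal genes were negative for 9 of 11 (median -0.93; adjusted p = 0.00325, and adjusted p = 0.578 with an estimated correlation). All 83 ribosomal protein genes had negative interaction values (median -0.34), with 0 passing over all genes or adjusted over the list alone; adjusted p = 3.44e-23 at the preset correlation became adjusted p = 0.578 with an estimated correlation. These list counts depended on library Shocked_High 3. Among shocked High heads it had the highest score for each list refitted below. Leaving it out therefore makes the interaction values more negative by construction, and the larger counts are not added support. Without Shocked_High 3, 73 of 83 ribosomal and 3 of 30 oxidative phosphorylation genes were lower adjusted over the list alone (ribosomal median -0.43). The antennal list then had 1 gene lower over all genes and 5 over the list alone, the detoxification list 1 and 9, and the starvation and sugar list 0 and 4. Leaving out Shocked_High 2 instead gave smaller antennal values, from -0.93 to -0.68 for lush and from -1.38 to -1.11 for Obp83a.

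Between naive High and naive Mid heads no gene passed (0 higher, 0 lower) in edgeR, DESeq2 or limma. Only 317 genes had an unadjusted p under 0.05 against 514 by chance. The smallest p belonged to CG5726 (48.5 ± 4.75 against 62.0 ± 4.35 CPM; log2 fold change -0.35, SE 0.08), CG8204 (0.71, SE 0.19) and shd, an ecdysone hydroxylase gene (-2.29, SE 0.59). None passed (smallest adjusted p 0.63, with all 7 and all 7 libraries on the side of the difference). No list had a member passing over all genes or adjusted over the list alone. All 30 oxidative phosphorylation genes had positive values (median 0.09), as did 82 of 83 ribosomal protein genes (0.09) and 20 of 21 photoreceptor genes (0.07). Their adjusted p values of 4.98e-09, 3.97e-05 and 0.00193 at the preset correlation became adjusted p = 0.578, adjusted p = 0.781 and adjusted p = 0.578 with an estimated correlation.

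Among shocked flies, 7 genes were lower in High than in Mid heads, among them Lsp2, Nmdmc, Ugt35b and Pex5. Lsp2 (FBgn0002565; dm6 chromosome 3L, 12129393 to 12131869), a hexamerin storage protein of the fat body, averaged 24.3 ± 20 CPM in shocked High (SD, n = 6) and 653 ± 794 CPM in shocked Mid heads (n = 8), a log2 fold change of -4.74 (SE 0.94). CR11538 (FBgn0017424; dm6 chromosome 3L, 12129103 to 12131488) had -4.84 (SE 0.95); it overlaps Lsp2 on the opposite strand, and since the strand setting is not given in the sources used here, reads of the 2 genes cannot be separated. Nmdmc fell by 1.81 on the log2 scale (SE 0.34; 27.4 ± 9.93 against 95.9 ± 65.2 CPM).

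Ugt35b (FBgn0026314; dm6 chromosome 3R, 11168503 to 11170246) averaged 36.0 ± 8.37 CPM in shocked High and 61.0 ± 11.3 CPM in shocked Mid heads (log2 fold change -0.76, SE 0.15). Pex5 (FBgn0023516; dm6 chromosome X, 1866832 to 1869061), the import receptor of peroxisomes, averaged 33.5 ± 6.81 and 51.6 ± 5.88 CPM (-0.62, SE 0.12). These 5 genes had an adjusted p of 0.0245 each in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with all 6 High and all 8 Mid libraries on the side of the difference. Under the 7 alternatives all of them passed, with adjusted p from 0.000213 to 0.0451 for Nmdmc and from 1.98e-06 to 0.0389 for Lsp2. The other 2 passing genes fell outside the naming rule and were chosen after their values were seen. They were CG16758 (FBgn0035348; dm6 chromosome 3L, 2499372 to 2503606; -1.69, SE 0.35, adjusted p = 0.0354) and CG10516 (FBgn0036549; dm6 chromosome 3L, 15968204 to 15969902; -0.89, SE 0.19, adjusted p = 0.0447). CG10516 was lost when only the groups compared were fitted (adjusted p = 0.0553).

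In edgeR, 0 genes were higher and 7 lower in shocked High than in shocked Mid heads, and 1797 had an unadjusted p under 0.05 against 514 by chance. DESeq2 called 310 genes (84 higher, 226 lower) and limma 668 (203 higher, 465 lower). A fit of only the groups compared called 67 (21 higher, 46 lower) and the replicate block 748 (196 higher, 552 lower). The count was 0 without Shocked_High 1, Shocked_High 2, Shocked_High 4, Shocked_High 5, Shocked_Mid 5 or Shocked_Mid 6. It was 548 without Shocked_High 3 (159 higher, 389 lower), 91 without Shocked_Mid 8, 33 without Shocked_Mid 7, 18 without Shocked_Mid 2 and 12 without Shocked_High 6. Single calls were also lost for Pex5 without Shocked_High 6 (adjusted p = 0.0515), CG16758 without Shocked_Mid 3 (0.0623) and CG10516 without Shocked_High 6 (0.0577) or Shocked_Mid 1 (0.0559). With the fat body score as a covariate the count was 0. Lsp2, which is itself part of the score, went from -4.74 (SE 0.94) to -2.11 (SE 0.62), Nmdmc from -1.81 (SE 0.34) to -1.42 (SE 0.39), Ugt35b from -0.76 (SE 0.15) to -0.61 (SE 0.16) and Pex5 from -0.62 (SE 0.12) to -0.41 (SE 0.13).

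The fat body list held 1 of 11 members lower over all genes (Lsp2) and 8 lower adjusted over the list alone, including the desaturase gene Desat1 (-1.09, SE 0.31), the nuclear receptor gene Hnf4 (-0.41, SE 0.14) and Lsd-2, a lipid droplet protein (-0.59, SE 0.20). Over the 11 genes the median was -0.61 (adjusted p = 3.97e-05 at the preset correlation, adjusted p = 0.578 with an estimated correlation). The fat body score was 7.59 ± 0.49 in shocked High and 8.60 ± 0.47 in shocked Mid heads (difference -1.01, exact permutation p = 0.00133, adjusted p = 0.00532 over 8 tests). Values were positive for 15 of 17 pan-neuronal genes (median 0.17), 19 of 24 monoamine genes (0.13) and 13 of 15 muscle genes (0.14), with 0 members passing over all genes or adjusted over the list alone. Their adjusted p values of 0.00436, 0.00839 and 0.0109 at the preset correlation became adjusted p = 0.645, adjusted p = 0.578 and adjusted p = 0.637 with an estimated correlation. Without Shocked_High 3 the pan-neuronal median was 0.27, with 3 of 17 genes higher over all genes and 10 over the list alone. Shocked_High 3 had the lowest pan-neuronal score of the shocked High heads (7.877), so leaving it out raises these values by construction. Of 12 glial genes, 9 were negative (median -0.05; adjusted p = 0.554 at the preset correlation). The detoxification list held 1 of 18 lower over all genes (Ugt35b) and 12 lower adjusted over the list alone, including Cyp6w1 (-1.14, SE 0.25), Cyp6g1 (-0.80, SE 0.20) and Sod (-0.37, SE 0.10). Its median was -0.43 (adjusted p = 7.87e-08 at the preset correlation, adjusted p = 0.578 with an estimated correlation). Of 19 starvation and sugar genes, 7 were lower adjusted over the list alone, with 0 over all genes. CG10924 (-1.58, SE 0.38), Amy-d, an amylase gene with a near-identical copy (-1.62, SE 0.52), the fructose bisphosphatase gene fbp (-1.03, SE 0.34) and the trehalose synthesis gene Tps1 (-1.12, SE 0.37) were among them. That list's median was -0.42 (adjusted p = 0.00215 at the preset correlation, adjusted p = 0.578 with an estimated correlation).

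**Figure D2:**
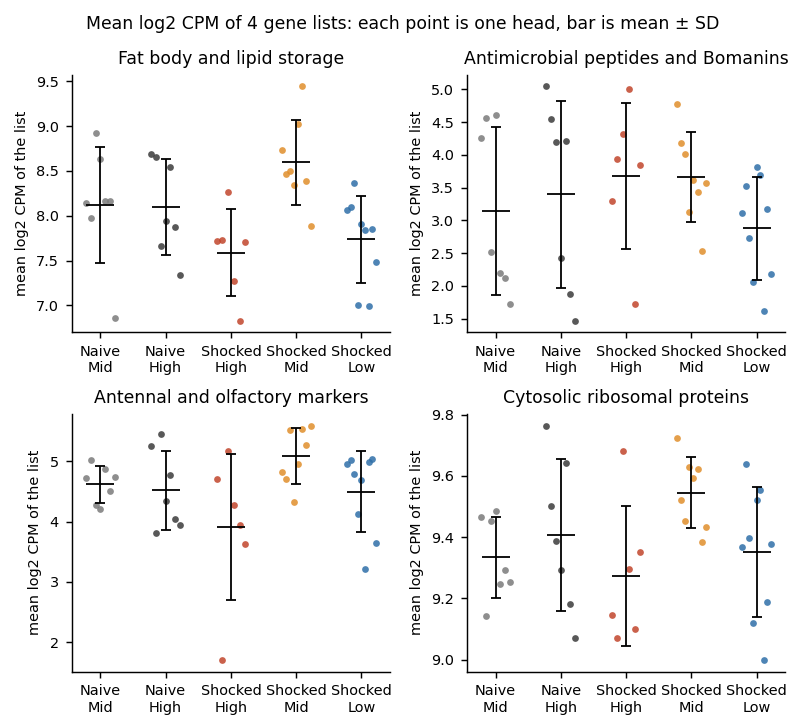
Mean log2 CPM of the fat body, antimicrobial peptide, antennal and ribosomal protein lists in each head, by group. The fat body score averaged 8.60 in shocked Mid, 7.59 in shocked High and 7.74 in shocked Low heads.

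Of 11 antennal genes, 6 were lower in shocked High than in shocked Mid heads adjusted over the list alone, with 0 over all genes. They included Ir8a (-3.27, SE 0.80) and the odorant-binding protein genes lush (-1.23, SE 0.42), Obp83b (-1.46, SE 0.54) and Obp83a (-1.43, SE 0.54). Antennal genes had a median of -1.14 (adjusted p = 0.000152 at the preset correlation, adjusted p = 0.578 with an estimated correlation). Without Shocked_High 3, 5 were lower over all genes and 7 over the list alone (median -1.61). That head had the highest antennal score of the shocked High heads (5.177), so leaving it out widens the difference by construction. Library Shocked_High 2 had the lowest value of all 37 libraries for 7 of these 11 genes, and without it only Ir8a passed adjusted over the list alone (1 gene; -2.99). The other 5 genes kept negative values without it: lush -0.97, Obp83a -1.16, Obp83b -1.19, Obp28a -1.10 and Obp19a -0.86 (edgeR adjusted p = 0.0559 to 0.0881 over the list alone).

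Adjusted over the list alone, other genes lower in shocked High than in shocked Mid heads were SPE (-0.69, SE 0.19) and GNBP3, which recognises fungal glucans (-0.91, SE 0.28), 2 of 20 immune genes. The photoreceptive clock gene cry (-0.33, SE 0.09) was 1 of 11 clock genes, Indy, a citrate transporter (-0.40, SE 0.13), was 1 of 12 glial genes, and fit (-1.97, SE 0.72) was 1 of 4 sex-biased genes. With all 37 libraries none of these lists had a member passing over all genes. The sex-biased list had a median of 0.07 and a mean of -0.39. The antimicrobial list had 0 members passing over all genes or adjusted over the list alone, with a median of 0.04, a mean of 0.32 and a downward camera direction (adjusted p = 0.259). All 83 ribosomal protein genes had negative values (median -0.26), with 0 passing over all genes or adjusted over the list alone; adjusted p = 7.93e-22 at the preset correlation became adjusted p = 0.578 with an estimated correlation. Without Shocked_High 3, 34 of the 83 were lower over all genes and 77 over the list alone (median -0.34); without Shocked_Low 8, 38 were lower over the list alone. Leaving out Shocked_High 3 also gave genes lower over all genes in the detoxification list (7 of 18), the starvation and sugar list (5 of 19), the immune list (3 of 20) and the fat body list (2 of 11). Among shocked High heads, Shocked_High 3 had the highest score for the ribosomal list and for each of these lists. Leaving it out therefore widens the differences by construction, and the larger counts are not added support.

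Shocked Low heads also had less Nmdmc than shocked Mid heads, 25.0 ± 8.75 CPM (SD, n = 9) against 95.9 ± 65.2 CPM (n = 8). Ppt2 (FBgn0032358; dm6 chromosome 2L, 11280298 to 11281920), a palmitoyl-protein thioesterase, fell from 41.4 ± 7.71 CPM in Mid to 28.5 ± 2.71 CPM in Low heads. Nmdmc had a log2 fold change of -1.94 (SE 0.30, adjusted p = 0.0014; 2.46e-06 to 0.0373 over the alternatives) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ppt2 had -0.54 (SE 0.10, adjusted p = 0.0471; 0.00404 to 0.0774 over the alternatives). All 9 Low and all 8 Mid libraries lay on the side of the difference for both genes. The Ppt2 call was kept in 5 of the 7 alternatives and was lost with the replicate block and when only the groups compared were fitted. The comparisons of shocked Mid with naive Mid, shocked High and shocked Low heads share the same 8 libraries and therefore their chance values, so the repeated call of Nmdmc is not independent.

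Between Low and Mid heads edgeR called 2 genes (0 higher, 2 lower), and 1436 genes had an unadjusted p under 0.05 against 514 by chance. DESeq2 called 150 genes (19 higher, 131 lower) and limma 6 (0 higher, 6 lower). Nmdmc passed with each library left out. Ppt2 did not pass without Shocked_Mid 1 (adjusted p = 0.0867), Shocked_Mid 5 (0.226), Shocked_Mid 6 (0.175), Shocked_Low 2 (0.13), Shocked_Low 5 (0.167), Shocked_Low 6 (0.0522), Shocked_Low 7 (0.0604), Shocked_Low 8 (0.1) or Shocked_Low 9 (0.0753), which left a count of 1. The count was 52 without Shocked_Low 3 (17 higher, 35 lower), 41 without Shocked_Mid 8 (3 higher, 38 lower), 9 without Shocked_Low 4 and 6 without Shocked_Mid 7. With the fat body score as a covariate it was 0, as Nmdmc went from -1.94 (SE 0.30) to -1.62 (SE 0.33) and Ppt2 from -0.54 (SE 0.10) to -0.30 (SE 0.10).

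Of 11 fat body genes, 9 were lower in Low than in Mid heads adjusted over the list alone, with 0 over all genes. They included Lsp2 (-3.19, SE 0.73), the lipase gene bmm (-0.75, SE 0.22), Desat1 (-0.93, SE 0.27) and the apolipophorin gene Rfabg (-1.01, SE 0.32). The list's median was -0.76 (adjusted p = 3.56e-06 at the preset correlation, adjusted p = 0.578 with an estimated correlation). The fat body score was 7.74 ± 0.48 in shocked Low heads (difference -0.86, exact permutation p = 0.00132, adjusted p = 0.00532 over 8 tests). Of 18 detoxification genes, 5 were lower adjusted over the list alone, with 0 over all genes, including Cyp6w1 (-0.89, SE 0.22), Ugt35b (-0.51, SE 0.13), Cyp4e2 (-0.68, SE 0.21) and Sod (-0.27, SE 0.09). CG10924 (-1.57, SE 0.33) and fbp (-0.94, SE 0.30) were 2 of 19 starvation and sugar genes lower adjusted over the list alone, with 0 over all genes.

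Of 26 antimicrobial peptide and Bomanin genes, 0 passed between Low and Mid over all genes, and 4 were lower and 1 higher adjusted over the list alone. CG43202 (-1.31, SE 0.36), CG5778 (-0.58, SE 0.17) and IM10 (-0.96, SE 0.34) were lower and Def was higher (4.20, SE 1.45). For Def only 5 of 9 Low and 5 of 8 Mid libraries lay on the side of the difference. Over the 26 genes the median was -0.96 (adjusted p = 6.08e-06 at the preset correlation, adjusted p = 0.578 with an estimated correlation). Of 20 immune genes, 0 passed over all genes and GNBP3 (-0.91, SE 0.25), SPE (-0.64, SE 0.17), Dif, a transcription factor of the Toll pathway (-0.28, SE 0.09), and nec (-0.54, SE 0.18) were lower adjusted over the list alone.

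Adjusted over the list alone, the genes higher in Low than in Mid heads included Hsp70Bc (1.16, SE 0.30) and the co-chaperone gene stv (0.23, SE 0.08), 2 of 11 heat shock genes. The clock gene per (0.32, SE 0.09) was 1 of 11 clock genes, and Yp1 (0.41, SE 0.12) and Yp3 (0.21, SE 0.08) were 2 of 4 sex-biased genes, whose median was 0.20 and mean -0.08. Among 24 monoamine genes Vmat was higher (0.22, SE 0.07) and Hn, phenylalanine hydroxylase, was lower (-0.96, SE 0.29), and among 12 glial genes Indy was lower (-0.45, SE 0.11). None of these lists had a member passing over all genes. Of 83 ribosomal protein genes, 82 had negative values (median -0.18), with 0 passing over all genes or adjusted over the list alone; adjusted p = 9.71e-17 at the preset correlation became adjusted p = 0.579 with an estimated correlation. Library Shocked_Low 8 was the lowest of all 37 for 46 of 83 ribosomal, 5 of 11 fat body and 7 of 26 antimicrobial genes. Without it the medians between Low and Mid were -0.16, -0.71 and -0.86, with 8 fat body genes lower, and 2 antimicrobial genes lower and 1 higher, adjusted over the list alone. The immune list then had 2 genes lower and the monoamine list 0 passing. All 11 antennal genes had negative values between Low and Mid (median -0.55), with 0 passing over all genes or adjusted over the list alone; adjusted p = 0.0045 at the preset correlation became adjusted p = 0.591 with an estimated correlation.

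Between shocked Low and shocked High heads no gene passed (0 higher, 0 lower) in edgeR, DESeq2 or limma, and 452 genes had an unadjusted p under 0.05 against 514 by chance. The smallest p belonged to dgt2, an augmin subunit gene (14.2 ± 1.98 CPM in Low, 9.55 ± 2 CPM in High; log2 fold change 0.58, SE 0.14), CG3987 (-0.52, SE 0.14) and Ude (0.46, SE 0.12). None passed (adjusted p 0.998 each; for dgt2 all 9 and all 6 libraries lay on the side of the difference). Of 26 antimicrobial peptide and Bomanin genes, 7 were lower in Low heads adjusted over the list alone, with 0 over all genes. CecA1 (-3.73, SE 1.07), AttA (-2.40, SE 0.84), AttB (-2.32, SE 0.81) and CecC (-2.71, SE 0.96) were among them; CecA1, AttA and AttB have near-identical copies and their counts are uncertain. These 26 genes had a median of -0.44 (adjusted p = 0.00015 at the preset correlation, adjusted p = 0.591 with an estimated correlation). Without Shocked_Low 8, 0 of them passed adjusted over the list alone (median -0.35). In Low against High heads the heat shock list (median 0.41), the muscle list (-0.20) and the haemocyte list (-0.17) had 0 members passing over all genes or adjusted over the list alone. Their adjusted p values of 0.00148, 0.000112 and 0.0264 at the preset correlation became adjusted p = 0.578, adjusted p = 0.578 and adjusted p = 0.637 with an estimated correlation. Shocked_Low 8 was the lowest library for 6 of 13 haemocyte genes, and without it that list's adjusted p = 0.451 at the preset correlation (median -0.10). Antennal genes had a median of 0.53 with 0 passing. Without Shocked_High 3 the median was 1.01 and 4 were higher adjusted over the list alone. That head had the highest antennal score of the shocked High heads, so leaving it out widens the difference by construction. Leaving out Shocked_High 2 instead, the library with low antennal genes, lowered the values of odorant-binding protein genes. They went from 0.63 to 0.37 for lush, 0.59 to 0.32 for Obp83a and 0.53 to 0.26 for Obp19a, with 0 passing.

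Across the 8 comparisons with all 37 libraries, the ribosomal, oxidative phosphorylation, muscle, pan-neuronal, neuropeptide, haemocyte and Turandot lists and the male dosage compensation RNAs had 0 members passing in any comparison, over all genes or adjusted over the list alone. Camera called 71 of 168 list tests at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.578; 10 tests at an unadjusted p under 0.05), and limma's fry called 0 (smallest adjusted p = 0.11).

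The authors' deposited table of 15947 genes had q-values under 0.05 for 525 genes between shocked High and shocked Mid, 283 between naive Mid and shocked Mid and 195 between shocked Mid and shocked Low. It had 9 such genes between naive High and shocked High, 2 between naive Mid and naive High and 0 between shocked High and shocked Low. Deposited log2 values are positive where the second-named group is higher, so the sign for shocked High against shocked Mid was turned before the correlation. Over the 10272 genes tested here, its log2 values correlated with those computed here at r = 0.9999 for shocked High against shocked Mid and for shock within Mid. The correlation was 0.9998 for Mid against Low and 0.9997 for High against Low. It was 0.9426 for shock within High and 0.9279 for the naive comparison, the 2 comparisons that contain naive High heads. Each of the 2, 7 and 2 genes called here within Mid, between shocked High and Mid, and between shocked Low and Mid had a deposited q under 0.05. For Nmdmc the deposited log2 value between naive Mid and shocked Mid was 1.81 (q = 0.00443). The 2 unused count columns, B3 and B4, carry the letter that the labels give to naive High libraries. Which libraries the authors used for each comparison is not given in the sources used here.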

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

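The tests of the antennal library were chosen after its values were seen, and the fat body and depth covariates were added after seeing the data. A value was singled out where the highest or lowest head of a group lay far from the others by Dixon's test. Chance flags about 1 in 20 groups; 14 of 229 groups tested were singled out, against 11.4 by chance, and they fell in 13 libraries.

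In log2 CPM, Rh5 was lowest at 8.42 in Naive_High 2 (nearest other 9.21) and at 9.15 in Shocked_Mid 6 (nearest 9.49), and Ir76b was lowest at 2.52 in Shocked_Mid 4 (nearest 3.6). Ir8a was highest at -0.34 in Shocked_High 3 (nearest -1.41). CG32506 was lowest at 4.91 in Naive_High 1 (nearest 5.2) and at 5.31 in Shocked_High 6 (nearest 5.58). CG5791 was highest at 5.95 in Naive_Mid 4 (nearest 4.53), and Sod was lowest at 8.58 in Naive_Mid 2 (nearest 8.92). Gclc was highest at 7.17 in Shocked_Mid 5 (nearest 6.95), and Indy was highest at 7.18 in Shocked_Mid 6 (nearest 6.65). Hsp70Bc was lowest at -0.42 in Shocked_Low 8 (nearest 1.05), and roX2 was lowest at 5.96 in Shocked_Mid 1 (nearest 6.35). Total counts were lowest at 6.1 M in Naive_Mid 1 (nearest 7.38) and highest at 11.32 M in Naive_High 3 (nearest 8.22).

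Shocked Mid heads stood apart from shocked High heads, with 315 genes at an adjusted p under 0.1. With total count as a covariate a median share of 1.026 of the log2 fold change was kept (quartiles 0.991 to 1.051), which argues against depth. With the fat body score as a covariate the median share kept was 0.529 (quartiles 0.2 to 0.754), 300 of 315 genes kept their sign, the standard error changed 1.06-fold and no gene passed at 0.05, so calls ended mainly because the fold changes shrank, with Lsp2 itself part of the score. More fat body RNA in shocked Mid heads and a response of the fat body or head to preference class cannot be told apart, because the score itself differs between these groups (7.59 against 8.60). The difference in place preference named by the design stays open as a biological explanation. Shocked Mid also stood apart from shocked Low heads, with 1436 genes at an unadjusted p under 0.05 against 514 by chance (fat body difference -0.86). Between shocked Low and shocked High heads there were 452 such genes and 0 called (fat body difference 0.15, exact permutation p = 0.56). By these unadjusted counts, shocked Mid differed more from both other shocked groups than those groups did from each other. No trend over Low, Mid and High and no contrast of Mid against the rest was fitted. Genes are correlated, so 514 is only a nominal chance level, and whether the pattern follows the order of the classes was not tested.

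Antimicrobial peptide levels differed widely between flies. With group means removed, the antimicrobial score rose with the fat body score over 37 libraries (r = 0.521, permutation p = 0.00262, adjusted p = 0.0157 over 6 relations; Spearman 0.482; r = 0.511 without the 2 most extreme libraries). Within single groups r was 0.356, 0.784, 0.553, 0.119 and 0.737 for naive Mid, naive High, shocked High, shocked Mid and shocked Low, with no adjusted p under 0.05, and it was -0.921 in shocked High without its 2 extremes. This is consistent with differing amounts of fat body in the heads (r = 0.521), found and tested on the same data. A difference in the score between the 5 groups cannot be told apart from chance (permutation p = 0.518), because the spread within groups is wide (SD 0.68 to 1.43) for 6 to 9 heads each.

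Antennal genes were low in library Shocked_High 2. By log2 CPM it was the lowest library for 7 of 11 antennal genes and for 0 of 21 photoreceptor genes. It had 37 raw counts of Obp83a (other libraries at least 341) and 2 of Obp19a (at least 72). Its total of 9.14 M, above the median of 7.65 M, argues against low depth. Other members were not low there: Ir25a had 70 counts (median of the other libraries 61), Ir76b 121 (86) and Obp56d 3974 (3054). Loss of the third antennal segment from that head may account for the 7 genes. This was proposed after the values were seen and checked only on the same values.

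Each comparison's count was set against 100 splits of the same libraries, the real one included. For shocked High against Mid 1 split gave as many (real 7, highest other 6) and for Low against Mid 1 split (real 2, highest other 1). For shock within Mid 2 splits did (real 2, highest other 4). Counts as large were rare among the splits here, but the shares were not adjusted over the comparisons and these share the shocked Mid libraries. The real 7 also counts Lsp2 and CR11538 separately, whose reads cannot be separated. Chance is therefore not excluded for these counts. For the pooled shock contrast 6 splits gave as many (real 1, highest other 1), so chance cannot be excluded for its count. For the 4 comparisons with a real count of 0, all 100 splits gave as many in shock within High, the interaction, naive High against Mid and Low against High. Their highest other splits called 383, 97, 44 and 3 genes, the first 2 of these in a single split. Such counts point to a structure of the samples beside the groups compared, which was not tested; only 5, 3, 3 and 3 of the 100 splits called any gene, so rare large counts among correlated genes are not excluded.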

How the results depend on the processing

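The covariates, leaving out each library, an adjusted p under 0.1 and DESeq2's default filtering target were chosen after seeing the data; the other alternatives were planned. Counts of 0 held under all alternatives for shock within High, naive High against Mid and Low against High. For the pooled shock contrast the main count of 1 became 8 with DESeq2 under either filtering target, 3 with limma, 2 with only the groups compared, 4 with the replicate block, 5 with the fat body score, 2 with total count and 4 at an adjusted p under 0.1. For shock within Mid 2 became 4 with no filter, 21 with DESeq2, 15 with its default target, 8 with limma, 14 with only the groups compared, 16 with the block (14 higher, 2 lower), 0 with the fat body score, 1 with total count and 4 at 0.1. The interaction count of 0 became 3 with DESeq2, stayed at 0 with its default target and became 2 with limma. For Low against Mid 2 became 7 with no filter, 150 with DESeq2, 100 with its default target, 6 with limma, 1 with the block, 0 with the fat body score, 1 with total count and 30 at 0.1. For High against Mid 7 became 13 with DESeq2's size factors, 12 with the strict filter, 310 with DESeq2, 287 with its default target, 668 with limma, 67 with only the groups compared, 748 with the block (196 higher, 552 lower), 0 with the fat body score, 21 with total count and 315 at 0.1. List calls went from 71 to 0 with an estimated correlation. The Ppt2 call in Low against Mid was lost with the block and with only the groups compared and kept in the other 5 of 7. The cause was not tested.

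With the fat body score as a covariate the sign turned for Hn (0.037), Desat1 (0.001), Rfabg (0.042) and fbp (0.02) in Low against Mid. It also turned for GNBP3 (0.055), Desat1 (0.067), Lsd-2 (0.026), fit (0.23), fbp (0.076) and Tps1 (0.132) in High against Mid. Desat1, Rfabg and Lsd-2 are members of the score, so their values near 0 follow from its construction; for the others the cause was not tested. With each library left out in turn, counts ranged from 1 to 5 for the pooled shock contrast, 0 to 0 within High, 0 to 6 within Mid, 0 to 4 for the interaction, 0 to 0 for naive High against Mid, 0 to 0 for Low against High, 1 to 52 for Low against Mid and 0 to 548 for High against Mid. By the number in the titles, which the block used, pairing was not evident. The 67 pairs of the same number had a median correlation of 0.018 (range -0.331 to 0.297, with 17 over 0.1), against -0.001 for 478 other pairs. Of 37 libraries, 7 correlated best with their own number. These values cannot exclude shared handling by number, and the block took High against Mid from 7 to 748 calls. Library names carry other numbers for some naive High and shocked Low heads, so the block did not follow the library numbers in these groups. By the library numbers, 59 pairs had a median of 0.017 (range -0.264 to 0.297, with 15 over 0.1). A block by library number was not fitted. With a median standard error of 0.12 to 0.137, changes of 1.41-fold were recovered in 41.5% to 55% of simulated genes, except for the interaction (20%) and the pooled shock contrast (73.6%). The simulated fits gave 110 to 178 calls against 0 to 7 in the real data, which eases the adjusted threshold. Recovery in the real data may therefore be lower.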

Other observations

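The tests in this part, including both lists of members and the boundary of 150 genes, were chosen after the top genes of shocked High against shocked Mid were seen. For genes of mitochondrial fatty acid oxidation, log2 values of shocked High against shocked Mid heads were -0.59 (SE 0.17) for whd, the carnitine palmitoyltransferase that brings fatty acids into mitochondria, and -0.67 (SE 0.18) for Mtpalpha, part of the trifunctional protein. They were -0.64 (SE 0.19) for colt, a carnitine carrier, and -1.08 (SE 0.31) for CG9547, an acyl-CoA dehydrogenase gene. None of these passed (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, smallest adjusted p of the list 0.0662 for CG12262). Genes of purine synthesis and one-carbon metabolism included Gnmt (-2.39, SE 0.63), ade5 (-1.34, SE 0.38), ade2 (-0.95, SE 0.23), Prat2 (-0.95, SE 0.24) and pug (-1.11, SE 0.38), with Nmdmc the only one of 21 members to pass.

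As a hypothesis, fatty acid oxidation and purine and one-carbon genes could be higher together in shocked Mid heads. Outside the 150 genes with the smallest p, 10 of 10 fatty acid oxidation members were lower in shocked High (share 1.0, binomial p = 0.000977; median -0.59), and 9 of 11 purine and one-carbon members were lower (share 0.818, p = 0.0327; median -0.66). Over all genes the share was 0.518. Members of a list are correlated, so the binomial p is too small; with an estimated correlation camera gave p = 0.0489 (correlation 0.756) and p = 0.0847 (correlation 0.338). Adjusted over both lists, camera gave adjusted p = 0.0847 for each. Both lists were chosen from the top genes of the same comparison and the members tested come from the same heads, so the shares of 1.0 and 0.818 cannot support or rank the hypothesis. They also do not separate a response to preference class from the difference in fat body score between the same groups.

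The first 3 principal components of log2 CPM held 17.6%, 6.7% and 5.1% of the variance. The first was led by CR11538, TotM, Diedel, Lsp2, TotC, TotA and fit, and the second by the antimicrobial peptide genes Dpt, Dro, Mtk, AttC and DptB. Shocked_Low 8 was the lowest library for 46 of 83 ribosomal protein genes, and Shocked_High 3 was the lowest for 10 of 17 pan-neuronal genes.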
